A study of Mus musculus with 15 samples.

How the data were processed

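Total RNA from mouse anterior prostate was measured on single-colour Illumina BeadArrays, 1 array per animal. Each array came from a different mouse, so the arrays of a group are biological replicates. Per the labels' protocols, RNA was extracted with a MagMAX-96 kit, checked on a Bioanalyser, amplified and labelled with biotin using a TotalPrep-96 kit.

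The values used were the authors' processed intensity values, deposited as 1 table of 45281 probes and 15 arrays. They are on a linear scale. The authors' background correction and normalization are not given in the sources used here. The array medians lay between 151.35 and 152.47 and the upper quartiles between 325.76 and 326.92, so the arrays had been brought to a similar scale before deposit, though their highest values still ranged from 43735.1 to 56678.2. The lowest values were above 100, so background had not been subtracted to 0 and folds of dim genes are understated. A further deposited table of signals that were not normalized has 15 columns named by chip and position only. Those 15 columns could not be tied to animals and were not used, and for the same reason the chip was not used as a batch. Only that table's gene symbol per probe was taken.

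Gene symbols were brought up to date through a RefSeq gene table of assembly GRCm38.p6, used for names alone. Of the probes, 27760 carried a current symbol, 7994 an older symbol of 1 gene, 187 an ambiguous symbol and 9340 an unmatched name, and the last 2 kinds were kept as deposited. These gave 28902 distinct names. The symbols are those of the array design and some can be outdated.

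The design fixed before the data were examined assumed raw signals with detection p-values, background correction by normexp and quantile normalization. Because the raw columns could not be tied to animals, the authors' values, planned as an alternative, became the main values. Detection was replaced by a limit from 1468 probes of olfactory and vomeronasal receptors, taken as silent in prostate. A probe counted as above background on an array when it exceeded that array's 95th percentile of these probes, which lay between intensities of 153.9 and 166.1. A probe was tested if it was above this limit on at least 3 arrays. This kept 24536 probes, and the probe with the highest mean log2 intensity stood for each of 16716 genes. Where a gene was not above the limit on any array of the dimmer group, the fold is given as "at least", computed from the mean of the brighter group and, per array of the dimmer group, the higher of the limit and the measured value.

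Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group over all 15 arrays, followed by eBayes with its moderated test (two-sided) and Benjamini-Hochberg adjustment over the tested genes. Residual degrees of freedom were 12. Genes with an adjusted p under 0.05 are called changed. Every adjusted p in the text comes from limma. The number of arrays limits the precision of each value.

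Gene lists, 35 in all, were written before the data were examined. They covered pathways, androgen-regulated genes, prostate cell types and other cell types that a dissected lobe could hold, and 923 of their 953 members were found on the array. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists of a comparison. The camera test with an estimated correlation and limma's fry were run beside it. The camera test compares a list with the other genes, whereas fry asks whether a list's genes move one way on balance.

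Genes were named by a rule fixed before the data were examined. Genes chosen in advance for the genotype, and some others that this rule names, are not reported here. Up to 10 higher and 10 lower genes per comparison (5 and 5 for castrated against control) had the largest fold among changed genes that were above background on every array of the brighter group and did not overlap between groups, leaving out clone and RIKEN names. Up to 4 members of each changed list, and of the PI3K-Akt-mTOR, androgen-regulated, luminal, basal and proliferation lists in any case, had the largest fold among changed members. Proliferation and neuroendocrine members that were not changed may be named with their values. Genes outside this rule are said to have been chosen after their values were seen.

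Chosen before the data were seen were fits with no filter on dim probes, the mean of a gene's probes, array weights, eBayes with trend and robust options, only the arrays compared, and fits without each array in turn or without 3 castrated animals whose ID numbers lie above 4000. Chosen after the data were seen were median scaling, quantile normalization, cyclic loess and normexp (offset 16) applied to the authors' values, stricter background limits (99th percentile, or 6 arrays), and leaving out arrays that stood apart. The planned fits that needed detection p-values, raw signals or chips were not run.

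The scripts were tested on simulated data made from the means and spreads of the 16716 genes, with known changes added. For mutant intact against control intact, 41 of 50 genes with a log2 change of 1 and 50 of 50 with a change of 2 were recovered, with 12 false calls. For mutant castrated against mutant intact, 47 of 50 genes with a change of 1 and 48 of 50 with a change of 2 were recovered, with 8 false calls. For mutant castrated against control intact these were 44 of 50, 48 of 50 and 15. Both shifted lists were recovered in all 3 comparisons, with 1 false list for castrated against mutant intact and 0 in the others. Figures were drawn with matplotlib.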

Results

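Gene expression was measured in the anterior prostate of 15 mice. Control mice (n = 3) were intact. Mice of a second genotype, which also carried floxed alleles and are called mutant here, were either intact (n = 6) or castrated (n = 6). The series concerns Akt and mTOR signalling in castration-resistant prostate cancer, and the 3 groups allow the mutant genotype and castration to be compared in untreated mice. Values are log2 intensities, given as mean ± SD, and log2 fold changes are given with their standard error (SE). Between 42.4% and 48.2% of probes were above background on an array. On the first principal component, which held 58.1% of the variance, the 3 control arrays lay between -90.24 and -83.21 and all 12 mutant arrays between 10.47 and 35.66.

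**Figure D1:**
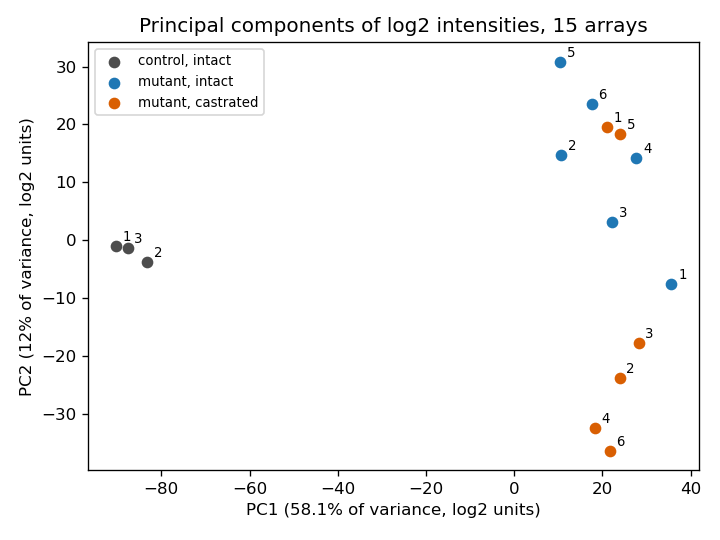
Principal components of the log2 intensities of the 16716 tested genes, 1 point per array, numbered by replicate within its group. The first component (58.1% of variance) parts the 3 control arrays from the 12 mutant arrays. On the second component (12% of variance) castrated replicates 1 and 5 lie at 19.56 and 18.42, among the mutant intact arrays.

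The first comparison asked how intact mutant prostate differed from intact control prostate. Ltf, which encodes the iron-binding protein lactoferrin, rose 181-fold from 7.60 ± 0.47 in control (n = 3) to 15.10 ± 0.51 in mutant intact (n = 6). Renin (Ren1) was at least 109-fold lower and the prostate transglutaminase Tgm4 fell 84.2-fold by the group means. Tgm4 lay between 15.43 and 15.65 in control but varied widely between mutant intact animals. It was 13.20 in replicate 2 and 10.78 in replicate 6, against 7.18 to 8.38 on the other mutant intact arrays. As a list, markers of proximal luminal cells rose, with and without an estimated correlation (adjusted p = 0.0222 with it).

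The largest increases after Ltf were in Reg3b (at least 103-fold), Dmbt1 (at least 66.9-fold), Nupr1 (69.4-fold), Ly6d (67.5-fold), Wfdc18 (at least 50.2-fold), Cxcl17, Wfdc2 (54.2-fold), Reg3g (at least 36.6-fold) and Pglyrp1 (48.2-fold). Reg3b and Reg3g encode antimicrobial lectins, and Pglyrp1 a peptidoglycan recognition protein. Nupr1, a stress-induced chromatin protein, measured 15.48 ± 0.11 in mutant intact (log2 fold change 6.12, SE 0.09, limma adjusted p = 1.05e-15). Among the largest decreases beside Ren1 were the lipase-related gene Pnliprp1, Pate9 (90.0-fold), Tgm4, the proton pump gene Atp12a (62.2-fold), Gsdma (61.8-fold), the metallothionein Mt3, Fgl1 (44.4-fold) and Ms4a5 (33.7-fold). Pnliprp1 and Mt3 were above background on 2 and 1 of 6 mutant intact arrays, so no fold is given for them. Folds depended on the settings of the fit. Over 27 fits the log2 fold change ranged from 4.77 to 8.63 for Ltf, 3.96 to 8.91 for Reg3b, 3.08 to 7.33 for Pglyrp1, -8.41 to -4.51 for Ren1 and -7.20 to -5.91 for Tgm4, all called in every fit.

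**Figure D2:**
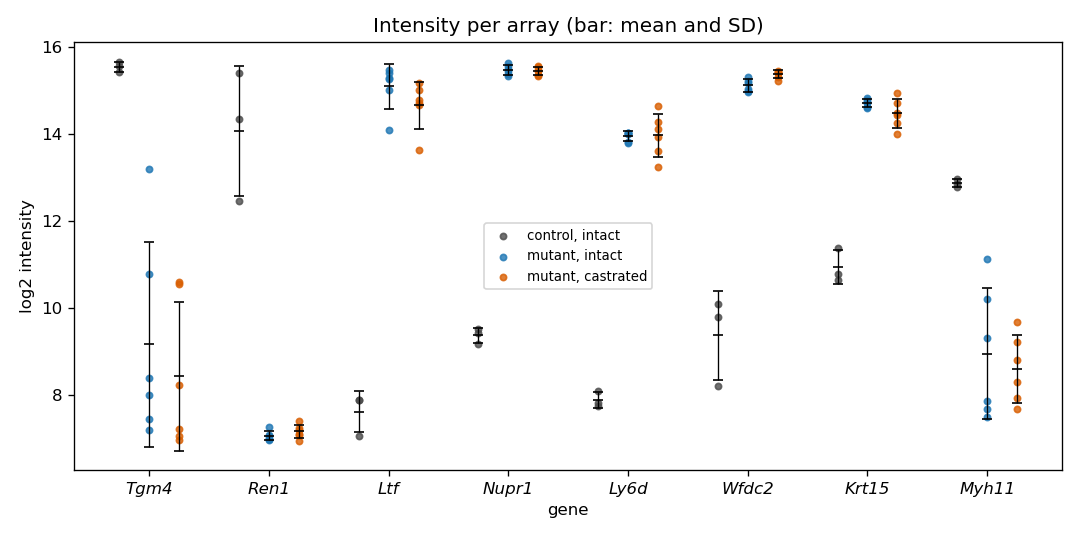
Log2 intensity per array (y axis) of 8 genes (x axis) in control intact (n = 3), mutant intact (n = 6) and mutant castrated (n = 6) mice, with bars for mean and SD. Ren1 and Myh11 were lower and Ltf and Nupr1 higher in every mutant array than in every control array.

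Of 20 tested markers of castration-tolerant proximal luminal cells, 18 rose and 0 fell (19 and 0 adjusted over the list alone, median log2 fold change 3.31, camera adjusted p = 2.75e-17, adjusted p = 0.0222 with an estimated correlation), led by Ltf and Wfdc2. Of 22 basal markers 15 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 4.87e-05, adjusted p = 0.11 with an estimated correlation), among them the keratins Krt15 (13.7-fold) and Krt17 (8.83-fold). The luminal list did not pass (camera adjusted p = 0.111), with 6 members higher, including Krt7 (14.8-fold), and 4 lower (7 and 4 adjusted over the list alone). Of 33 androgen-regulated genes 11 rose and 8 fell (the same adjusted over the list alone, camera adjusted p = 0.431). Their median was 0.29 and their mean -0.37, since some of the genes that fell, such as Tgm4 and Pbsn (at least 23.0-fold), fell far.

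Immune and inflammatory genes were higher. Of 23 macrophage and dendritic cell markers 20 rose (21 adjusted over the list alone, camera adjusted p = 6e-09, adjusted p = 0.273 with an estimated correlation), including the lipopolysaccharide co-receptor Cd14 (log2 fold change 3.91) and the complement gene C1qb (6.40-fold). Of 20 neutrophil and myeloid suppressor markers 12 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 5.14e-06, adjusted p = 0.233 with an estimated correlation), including S100a8 (at least 23.5-fold) and Lcn2 (25.7-fold). Ltf and Lcn2 are also made by epithelium. Of 32 interferon response genes 29 rose (the same adjusted over the list alone, camera adjusted p = 6.96e-15, adjusted p = 0.185 with an estimated correlation), among them Oas2 (at least 39.0-fold) and Ifit3 (37.0-fold). Of 33 inflammatory cytokine and NF-kB genes 25 rose (27 adjusted over the list alone, camera adjusted p = 1.62e-14, adjusted p = 0.0277 with an estimated correlation), led by the chemokines Cxcl17 and Cxcl15 (33.8-fold). In the T and NK cell list 11 of 23 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.515 with an estimated correlation), with Ccl5 4.04-fold and Cd3g 3.14-fold higher. The B cell and plasma cell list had 7 of 18 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.404 with an estimated correlation). Its immunoglobulin gene Iglv1 rose 5.72-fold, while Derl3, which belongs to protein degradation in the endoplasmic reticulum, fell 14.5-fold. Complement and acute phase genes rose in 13 of 18 cases and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 4.27e-06, adjusted p = 0.102 with an estimated correlation), with the immunoglobulin transporter Pigr 14.9-fold higher.

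Stromal markers went different ways. All 19 smooth muscle markers fell (the same adjusted over the list alone, median log2 fold change -1.74, camera adjusted p = 6.49e-09, adjusted p = 0.153 with an estimated correlation), including the myosin heavy chain Myh11 (15.3-fold) and desmin (Des, 11.9-fold). Of 26 fibroblast and matrix markers 5 rose, 1 fell and 20 were not called (camera adjusted p = 0.0304, adjusted p = 0.598 with an estimated correlation), with Igfbp5 3.88-fold and Col1a1 3.38-fold higher. Only 1 rose and 0 fell when adjusted over the list alone, and Col1a1 was not called in 12 of 27 fits. Of 19 endothelial markers 5 rose and 1, Emcn, fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.554 with an estimated correlation). Egfl7 was 1.81-fold higher and Emcn 4.05-fold lower. Transcripts of seminal vesicle secretion were unevenly spread within groups. Pate4, chosen after its values were seen, measured 15.44 and 15.38 in control replicates 2 and 3 and 7.64 in control replicate 1, and 15.38 in mutant intact replicate 3, with replicate 2 nearly as high, against 6.96 to 8.95 in the other 4.

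Growth and metabolic lists also moved. Of 32 proliferation genes 18 rose and 1 fell, and 22 rose when adjusted over the list alone (camera adjusted p = 1.36e-05, adjusted p = 0.32 with an estimated correlation). The centromere gene Cenpa rose 3.05-fold, Prc1 2.82-fold and Mki67 2.30-fold. Of 39 PI3K-Akt-mTOR components 20 fell and 5 rose (21 and 5 adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.0996 with an estimated correlation), with the mTOR inhibitor gene Deptor 4.25-fold lower. Glycolysis and hypoxia genes rose in 17 of 24 cases (the same adjusted over the list alone, camera adjusted p = 4.27e-06, adjusted p = 0.233 with an estimated correlation), including Egln3 (13.0-fold) and the carbonic anhydrase Car9 (6.28-fold), whose log2 fold changes were 1.73 and 1.37 with probes averaged. Growth factor receptor and MAPK feedback genes rose in 13 of 25 cases and fell in 1 (the same adjusted over the list alone, camera adjusted p = 7.02e-05, adjusted p = 0.0222 with an estimated correlation), with Phlda1 8.12-fold and the phosphatase Dusp4 4.54-fold higher. Of 20 senescence and p53 targets 11 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.0996 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose 5.93-fold and Gdf15 fell 7.71-fold. Glutathione and detoxification genes rose in 13 and fell in 5 of 31 cases (13 and 6 adjusted over the list alone, camera adjusted p = 0.00253, adjusted p = 0.11 with an estimated correlation), with Gpx2 13.4-fold higher.

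The secretory apparatus fell. Of 30 ER stress and secretory genes 25 fell and 1 rose (26 and 1 adjusted over the list alone, camera adjusted p = 1.75e-10, adjusted p = 0.0578 with an estimated correlation), among them Creld2 (6.96-fold) and Sdf2l1 (6.22-fold). In the polyamine and zinc-citrate list 7 of 17 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.185 with an estimated correlation), with Mt3 and the zinc transporter Slc30a2 (18.2-fold) lower. Of 34 ribosomal protein genes 27 fell by small amounts (28 adjusted over the list alone, camera adjusted p = 4.27e-06, adjusted p = 0.189 with an estimated correlation), Rpl4 by 1.86-fold. Mitochondrial oxidative phosphorylation genes fell in 11 and rose in 4 of 36 cases (the same adjusted over the list alone, camera adjusted p = 0.0441, adjusted p = 0.515 with an estimated correlation), a call that passed in 19 of 27 fits. The fibroblast list passed in 21 of 27, adipocyte in 22, endothelial in 23 and epithelial to mesenchymal transition in 24. Adipocyte markers rose in 4 and fell in 1 of 16 cases (3 and 1 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.273 with an estimated correlation), with Dgat2 16.7-fold and Pparg 7.40-fold higher. Genes of epithelial to mesenchymal transition rose in 8 and fell in 2 of 23 cases (the same adjusted over the list alone, camera adjusted p = 0.0284, adjusted p = 0.515 with an estimated correlation), with Cd44 9.75-fold and Mmp14 6.77-fold higher by their brightest probes. With a gene's probes averaged, their log2 fold changes were 1.83 and 1.43, and the other probe of Mmp14 was not called. None of 13 neuroendocrine markers was called (camera adjusted p = 0.521), and prostate secretory products as a list did not pass (camera adjusted p = 0.678). By fry, which asks whether a list moves one way on balance, prostate secretory products (adjusted p = 0.000905) and androgen-regulated genes (adjusted p = 2.19e-05) were lower.

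In all, 7283 of 16716 genes differed between mutant intact and control, 3042 higher and 4241 lower. Of these, 2191 changed at least 2-fold, 1330 higher and 861 lower. At an unadjusted p under 0.05, 8477 genes passed, where 836 would be expected by chance. Of the 35 lists, 24 were called, 18 higher and 6 lower, and 3 kept their call with an estimated correlation. Without the 4 intact arrays that were high in seminal vesicle transcripts, a choice made after seeing the data that leaves 1 control array and assumes that it varies like the others, 3661 genes were called.

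**Figure D3:**
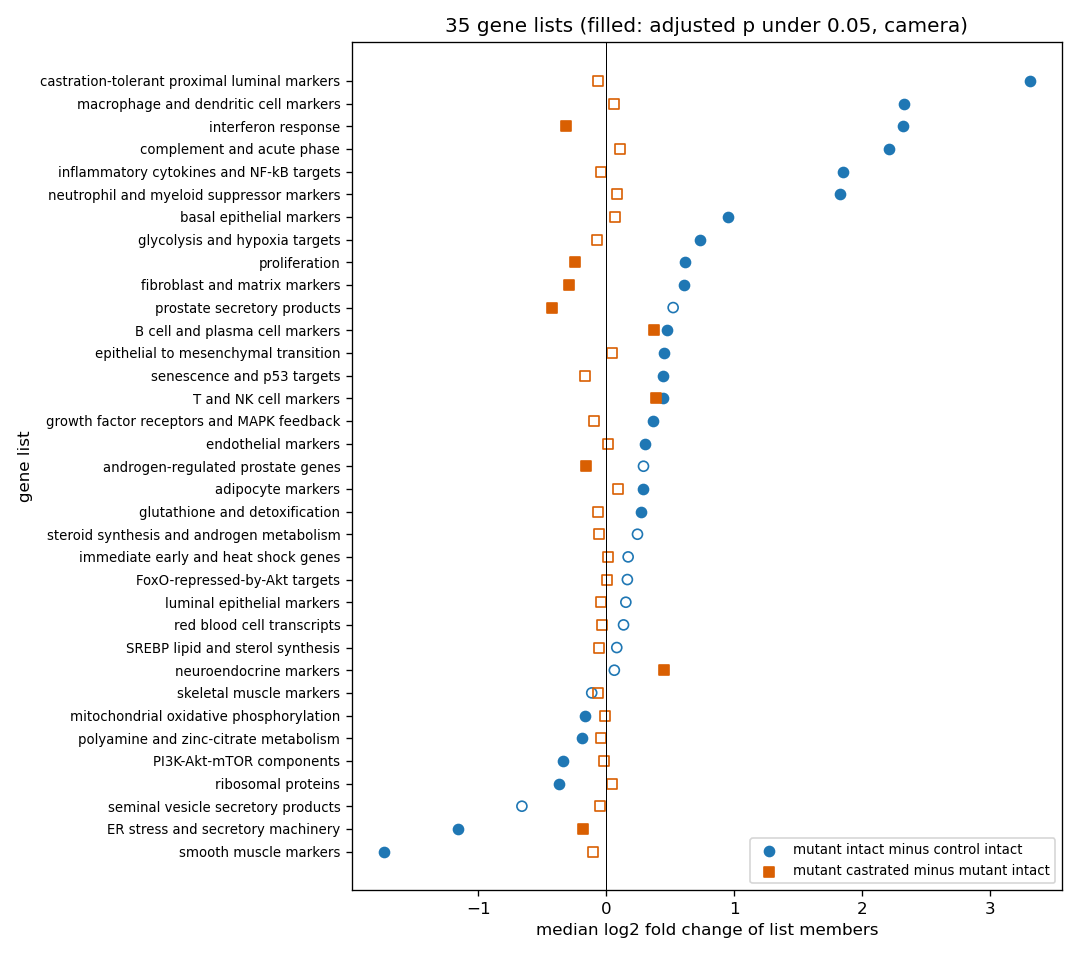
Median log2 fold change (x axis) of the tested members of 35 gene lists (y axis), for mutant intact minus control intact (circles) and mutant castrated minus mutant intact (squares), filled where camera's adjusted p was under 0.05. Proximal luminal markers had the highest median in the first comparison (3.31) and smooth muscle markers the lowest (-1.74), and medians in the second lay between -0.42 and 0.45.

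The next comparison asked how castration changed mutant prostate. No single gene passed the threshold (0 of 16716 by limma, smallest adjusted p = 0.0571), with 2620 genes at an unadjusted p under 0.05 where 836 would be expected by chance. The androgen-regulated genes Msmb and Azgp1 were low in 4 castrated arrays and not in the other 2. Msmb, which encodes a secreted prostate protein, measured 7.39, 7.11, 7.25 and 7.23 in castrated replicates 2, 3, 4 and 6, and 11.41 and 12.85 in castrated replicates 1 and 5. In mutant intact it lay between 10.47 and 12.69 on 5 arrays and at 7.31 in replicate 1, where Fkbp5 was 11.80. Azgp1, a secreted lipid-mobilizing protein, lay between 7.20 and 8.28 in those 4 arrays, and at 11.67 and 9.91 in replicates 1 and 5.

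Over all 6 castrated arrays, Msmb differed from mutant intact by a log2 fold change of -1.96 (SE 1.19, limma adjusted p = 0.453), Azgp1 by -1.64 (SE 0.73, limma adjusted p = 0.293), the androgen-induced chaperone gene Fkbp5 by -1.59 (SE 0.37, limma adjusted p = 0.09), Spink1 by -2.20 (SE 0.83, limma adjusted p = 0.226) and Mme by -1.09 (SE 0.51, limma adjusted p = 0.32). These 5 genes were chosen after their values were seen.

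**Figure D4:**
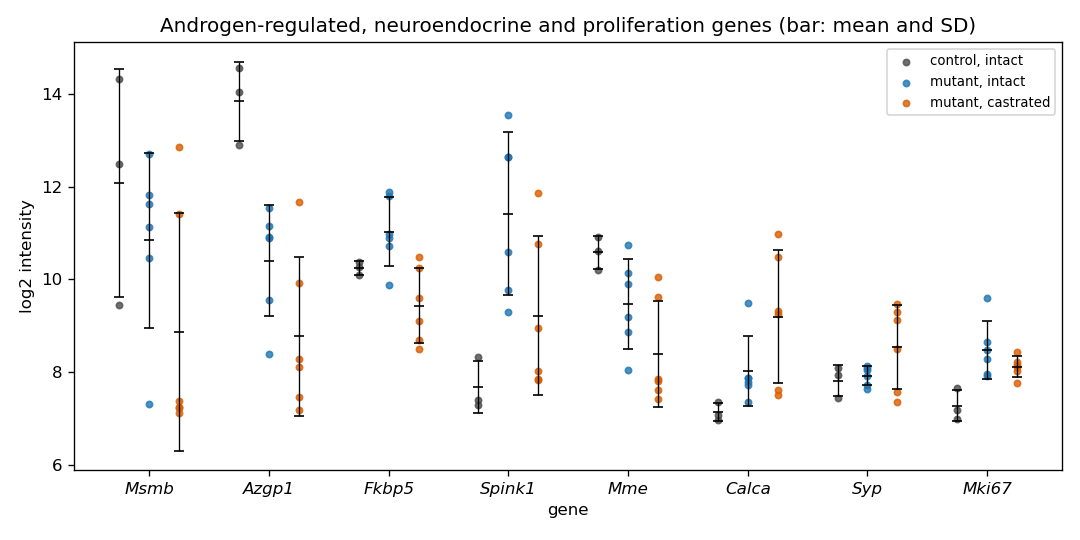
Log2 intensity per array (y axis) of 5 androgen-regulated genes, 2 neuroendocrine genes and the proliferation gene Mki67 (x axis) in the 3 groups, with bars for mean and SD. The castrated arrays fall apart for Msmb, with 4 between 7.11 and 7.39 and 2 at 11.41 and 12.85.

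Of the 35 lists, 9 passed camera's preset test, and none of the 9 did with an estimated correlation or by fry. The androgen-regulated list was lower (median log2 fold change -0.16, camera adjusted p = 0.0276, adjusted p = 0.348 with an estimated correlation), as were prostate secretory products (median -0.42, camera adjusted p = 0.000125, adjusted p = 0.348 with an estimated correlation) and ER stress and secretory genes (median -0.18, camera adjusted p = 1.59e-05, adjusted p = 0.348 with an estimated correlation). Adjusted over the list alone, 1 androgen-regulated gene and 1 ER stress and secretory gene fell. The proliferation list was lower (median -0.24, camera adjusted p = 7.98e-05, adjusted p = 0.586 with an estimated correlation). Its members Mki67 and Top2a had log2 fold changes of -0.36 (limma adjusted p = 0.489) and -0.29 (limma adjusted p = 0.612). Mutant intact replicate 1 was the highest array for both (9.60 and 9.42), and without it these were -0.14 and -0.12. The interferon list was lower (median -0.32, camera adjusted p = 0.000563, adjusted p = 0.798 with an estimated correlation), a call lost in 2 of 27 fits. Its members Ifit3 and Oas2 were looked at per array after their values were seen. Ifit3 (10.60 and 11.64) and Oas2 (9.76 and 10.43) were low in castrated replicates 4 and 6 alone, with the other 4 castrated arrays at 13.46 to 14.64 and 12.77 to 13.32. Also lower was the fibroblast list (median -0.29, camera adjusted p = 0.0486, adjusted p = 0.887 with an estimated correlation), which passed in only 12 of 27 fits. The androgen-regulated list passed in 22 of 27.

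Higher in mutant castrated were T and NK cell markers (median 0.39, camera adjusted p = 0.000125, adjusted p = 0.586 with an estimated correlation), B cell and plasma cell markers (median 0.37, camera adjusted p = 0.00154, adjusted p = 0.481 with an estimated correlation) and neuroendocrine markers (median 0.45, camera adjusted p = 0.000676, adjusted p = 0.586 with an estimated correlation). Among neuroendocrine genes, Calca, which encodes calcitonin gene-related peptide, had a log2 fold change of 1.17 (SE 0.55, limma adjusted p = 0.317), the synaptic vesicle gene Syp one of 0.62 (SE 0.33, limma adjusted p = 0.371) and Chga one of -0.02 (limma adjusted p = 0.985). No neuroendocrine member passed when adjusted over the list alone (0 of 13). Castrated replicates 1 and 5 were the lowest castrated arrays for the T cell genes Cd3g (9.02 and 9.14, others 9.61 to 10.07) and Ccl5 (10.22 and 10.72, others 11.05 to 12.09), chosen after their values were seen. They also stood apart among neuroendocrine genes, with Calca at 7.62 and 7.51 against 9.26 to 10.99 in the other 4, and Syp at 7.56 and 7.35 against 8.49 to 9.46.

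The count of 0 genes depended on single arrays. It was 268 without castrated replicate 1, 234 without castrated replicate 5 and 617 with array weights.

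The last comparison set castrated mutant against intact control prostate, groups that differ in both genotype and castration. The genes with the largest changes were largely those seen in intact mice. Ltf rose 134-fold, the carbonic anhydrase Car12 at least 73.2-fold, Ly6d 68.6-fold, Nupr1 68.2-fold and Reg3g at least 50.2-fold. Pate9, Tgm4, Ren1 and Atp12a fell, Atp12a 88.4-fold. Pate9, Tgm4 and Ren1 were above background on 2, 3 and 1 of 6 castrated arrays, so no fold is given for them.

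Many of the same lists were called. Proximal luminal markers rose in 17 of 20 cases (the same adjusted over the list alone, camera adjusted p = 2.53e-15, adjusted p = 0.0347 with an estimated correlation), interferon genes in 27 of 32 (28 adjusted over the list alone, camera adjusted p = 5.92e-12, adjusted p = 0.266 with an estimated correlation), and T and NK cell markers in 15 of 23, with 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 0.000468, adjusted p = 0.382 with an estimated correlation). All 19 smooth muscle markers fell (the same adjusted over the list alone, camera adjusted p = 3.51e-09, adjusted p = 0.176 with an estimated correlation), as did 27 of 30 ER stress and secretory genes (the same adjusted over the list alone, camera adjusted p = 1.13e-12, adjusted p = 0.0347 with an estimated correlation). The neuroendocrine list was higher (camera adjusted p = 0.0411, adjusted p = 0.549 with an estimated correlation), with Calca at least 3.54-fold and Ddc at least 1.26-fold higher and 11 of 13 members not called. The list passed in 15 of 27 fits, and none of the 3 other probes of Calca was called. When adjusted over the list alone, 0 neuroendocrine members passed.

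In this comparison 7449 of 16716 genes changed, 3336 higher and 4113 lower, and 22 of 35 lists were called, 4 of them also with an estimated correlation. With the mutant intact comparison it shared 2578 higher genes, where independent lists would share 607, and 3547 lower genes, where they would share 1044, and 0 genes were called in opposite directions. Both comparisons use the same 3 control arrays. In 20 simulations of unchanged groups, with every array and gene drawn as independent noise, no shared call was made. Few calls of any kind come from such noise, so that count decides nothing. The covariance of the log2 fold changes was 0.69, against 0.0303 from independent noise in the shared arrays alone. Such noise accounts for little of the covariance. A trait common to the 3 real control arrays was not modelled and stays possible.

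How far castration moved the mutant differences back toward control was measured as the covariance between the first and the second comparison. It was -0.0192, of which -0.0151 is given by the shared mutant intact arrays alone, leaving -0.004. With the 6 mutant intact arrays split between the comparisons in all 20 ways, the median covariance was -0.0033 (range -0.0367 to 0.0563), and the median share of genes with the same sign in both was 49.2% (45.1% to 55.4%). The corrected value lay within its jackknife standard error of 0.0243.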

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

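All tests of explanations in this part were chosen after the results were seen. Of 156 groups of 6 arrays examined gene by gene, 13 had 1 array far from the other 5, where 8 would be expected by chance (about 1 in 20). Mutant intact replicate 1 was highest for C1qb (14.72) and lowest for Dgat2 (11.04), Igfbp5 (13.64) and Pparg (9.46). Mutant intact replicate 2 was lowest for Dmbt1 (11.76) and Ltf (14.11) and highest for Pnliprp1 (8.87). Mutant intact replicate 3 was highest for Ren1 (7.26), replicate 5 lowest for Ifit3 (13.09) and replicate 6 highest for Calca (9.50). In mutant castrated, replicate 1 was lowest for Pnliprp1 (7.12), replicate 2 lowest for Ltf (13.64) and replicate 3 highest for Cd44 (12.99).

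Castrated replicates 1 and 5 carried Msmb and Azgp1 at intact levels. An exchange of labels with mutant intact arrays would need partners at castrated levels, and 0 of the 6 mutant intact arrays had at least 3 of Msmb, Azgp1, Fkbp5, Spink1 and Mme at the level of the other castrated arrays. Mutant intact replicate 1 came close, with Msmb at 7.31 (others at most 7.39), Azgp1 at 8.39 (at most 8.28) and Mme at 8.04 (at most 7.86), but Fkbp5 at 11.80 and Spink1 at 10.59 were not low. A first form of this test used correlation over all genes, and by it 2 mutant intact arrays, replicates 1 and 4, lay nearer the castrated arrays (0.9453 against 0.9436, and 0.9743 against 0.9737), as an exchange would give. The test was changed to the 5 genes after that result was seen, so it argues against an exchange only weakly. A wrong label without a partner and androgen action that persisted in these animals cannot be told apart, as both predict that the 2 arrays correlate better with the mutant intact arrays, which 2 of 2 did. No hormone level was analysed here.

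Seminal vesicle transcripts were high in single arrays of each group. If seminal vesicle tissue had been carried into the sample, its other transcripts should be high in the same arrays. Of 11 other list members, 4 were higher in all 4 intact arrays with high Pate4, which leaves that explanation open. Castrated replicates 3 and 6 had Pate4 at 13.84 and 14.35, but Svs2 was above the background limit in 1 of them, and how castration acts on Svs2 in the vesicle was not measured here.

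Smooth muscle markers fell in mutant intact while other stromal lists did not. A lower share of all stroma is argued against by the fibroblast list, whose median log2 fold change was 0.61, though that list's rise was lost with an estimated correlation (camera adjusted p = 0.598). In a fit with Pate4 as a covariate, the smooth muscle median stayed at -1.64 (camera adjusted p = 3.79e-09). This argues only weakly against muscle carried along with seminal vesicle as the whole cause. Pate4 was not established as a mark of carried vesicle, and the fit used 1 slope over all 15 arrays. Mutant intact replicates 2 and 3, high in Pate4, were the highest mutant intact arrays for Myh11 (10.21 and 11.12, others 7.49 to 9.30). Control replicate 1, low in Pate4, had Myh11 at 12.78. The authors' normalization cannot be judged as a cause, since the 4 other scalings were applied to the authors' normalized values. Under them the median was at most -1.67. Median scaling and quantile normalization barely moved it (-1.739 and -1.738, from -1.737). A loss of muscle relative to epithelium in mutant tissue stays open as a hypothesis, since tissue composition was not measured.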

How the results depend on the processing

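Median scaling, quantile normalization, cyclic loess, normexp, the stricter background limits the fits without arrays that stood apart and the splits for genes in castrated against mutant intact were chosen after seeing the data. The gene counts against control were within 1.5 times under every alternative but 1. Without the 4 arrays high in seminal vesicle genes, the mutant intact count was 3661, 3551 of them also called with all arrays. Leaving out each array in turn gave 5986 to 7370 genes for mutant intact against control and 6113 to 7886 for castrated against control, and 19 to 24 and 18 to 23 lists. Castrated against mutant intact gave 0 to 268 genes and 6 to 14 lists. The 0 became 1 without a filter on dim probes and 617 with array weights. It became 1673 without castrated replicates 1 and 5, a count that says nothing about castration because these arrays were chosen by their expression. With an estimated correlation, 3, 0 and 4 lists were called in the 3 comparisons in the order reported, and fry called 28, 0 and 29. The reversal covariance ranged from -0.0156 to 0.0058 with single arrays left out. With cyclic loess, 51.3% of the genes changed in mutant intact were higher, against 41.8%, and 52.7% of those changed in castrated against control, against 44.8%, so the balance of directions depends on scaling. Other causes were not tested. No paired analysis was possible because the labels give no replicate numbers. Fits on raw signals, with detection p-values or with the chip as a block were not run. Intensity over background limits dim genes, whose folds are understated.

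Other groupings of the same arrays were tried. For mutant intact against control, 1 of 84 splits gave as many genes (7283, highest other 497), so random division of the arrays does not account for it, and 2 of 84 gave as many lists (24, highest other 25). For castrated against control, 1 of 84 gave as many genes (7449, highest other 217), and 5 of 84 gave as many lists (22, highest other 23), so chance is not excluded for that count of lists. For castrated against mutant intact, the count of 0 genes makes this uninformative, since any split gives as many (100 of 100, highest other 509). For lists, 67 of 100 gave as many (9, highest other 19), so chance is not excluded.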

Other observations

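The skeletal actin gene Acta1, chosen after its values were seen, measured 12.60 to 12.66 in the 3 control arrays, 7.10 to 10.10 in mutant intact and at most 7.24 in mutant castrated. Among mutant arrays it was highest in mutant intact replicates 2 and 3 (8.64 and 10.10), which had high Pate4. Castrated replicates 3 and 6 also had high Pate4 (13.84 and 14.35) but low Acta1 (7.24 and 7.04), and control replicate 1 had low Pate4 (7.64) with Acta1 at 12.63.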
